A study of Mus musculus with 6 samples.

How the data were processed

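Gene expression was measured by single-colour oligonucleotide array in total RNA of mouse placenta, with biotin as the label. The 6 arrays fell into 2 groups of 3 by their titles: placentas of pregnant mice that received saline (control) and placentas of pregnant mice that received dexamethasone, a synthetic glucocorticoid, at 0.5 mg/kg on gestational days 15, 16 and 17. Per the labels, each array stands for a set of pregnant mice. The labels do not say whether the RNA of several placentas or litters was pooled for an array, and they give no day of collection. The p-values therefore measure the spread between these 6 samples, which may be partly technical.

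The deposited table holds 1 linear intensity for each of 22626 probe sets on each array. The submitters' processing notes name GCOS, the array maker's operating software; its version and settings are not given in the sources used here. The values were never negative, and after 2% of the probe sets was cut at each end the mean intensity lay between 149.3 and 149.5 on all 6 arrays, so the arrays were kept as the authors scaled them. Array medians ran from 53.9 to 62.1. Detection calls and scanner images were not analysed here, so a dim intensity has no stated bound; between 20.8% and 24.3% of the probe sets on an array lay below 16. The number of arrays, 3 per group, limits the precision of every value.

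Probe sets were named through the platform's annotation, with gene identifiers looked up in the GRCm38.p6 gene table, which was used for names only. Of the 22626 probe sets, 20380 were paired with 1 gene, 691 with several genes and 1555 with no gene; probe sets of the last 2 kinds stayed in the test without a name. Of the named ones, 20351 were found in the gene table by their gene identifier, and 0 symbols had to be updated. Each array's column was matched to its sample by the sample's own label, and 0 columns were left unmatched. Control probe sets with names starting in AFFX numbered 0 in the table, so the planned comparison of 3-prime with 5-prime signals of Gapdh and Actb could not be made, and RNA integrity was not assessed. No coordinates are given, since the files name no genome build.

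Intensities were transformed as log2(signal + 16). Probe sets with a mean signal over the 6 arrays at or above the 40th percentile (39) were kept, which left 13577 probe sets for 8371 genes. A difference on this scale understates the change of dim genes. Dexamethasone was compared with control in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend; prior degrees of freedom 4.58), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The limma, camera and fry tests were two-sided. A gene was represented by its kept probe set of highest mean signal; 2786 genes had several kept probe sets, and 2 of them had probe sets called in opposite directions. An exact permutation test of 3 arrays against 3 has 20 arrangements and cannot give a p below 0.1, so single genes were not tested that way. It was run on the mean of each list per array, where it cannot pass the threshold either.

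Fixed gene lists numbered 35, and 34 of them had at least 5 measured genes; the sex-linked transcripts did not and served as a check of the arrays. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 34 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes measured. The directional p of fry asks whether the genes of a list move, on balance, the same way, its mixed p whether they change in either direction, and neither compares the list with other genes. The number of members past the threshold is given both over all probe sets kept and adjusted over the list alone.

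The groups, tests, gene lists, most of the alternative settings and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose signals on the 3 control and the 3 dexamethasone arrays do not overlap. It adds, from each list, the 4 members with the smallest p and every member past the threshold where there are 6 or fewer. It also takes Nr3c1, Hsd11b2, Fkbp5, Tsc22d3, Per1 and Sgk1 as treatment checks, and Igf2, Slc2a1, Slc2a3, Vegfa, Tpbpa and Prl3b1 as placental reference genes, whatever their values. Prl3b1 had no kept probe set of its own and is not reported. Members of small counts that fall outside the rule are named as chosen after their values were seen.

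The scripts were tested on simulated data made from the 13577 probe sets and the spread of these arrays. In 5 simulations with 200 changed probe sets each, the comparison of dexamethasone with control recovered 58.6% of those changed by 1 on the log2 scale and 94% of those changed by 2, and 3.30% of the probe sets called were false. All 25 simulated lists shifted by 0.5 were called, and 0 of 75 unshifted ones. The simulated probe sets varied independently and the lists were random, so false calls of lists whose genes vary together were not tested. In the real data the estimated correlation within a list reached 0.92, for the natural killer markers.

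Alternatives were pseudocounts of 1 and 64, quantile normalization, centring on the array median, no filter, a filter at the 60th percentile, eBayes without the trend and with robust variance, array weights, the replicate number as a block, and leaving out each array in turn. For the lists, the mean over a gene's probe sets, ranks and an estimated correlation were also tried. Cyclic loess normalization and the signal of Xist as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.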

Results

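Placental gene expression was compared between 3 arrays from saline-injected control mice and 3 arrays from mice given dexamethasone at 0.5 mg/kg on gestational days 15, 16 and 17. The comparison asks which placental transcripts differ after antenatal steroid treatment. Since the labels give no day of collection, a difference in gestational age cannot be told apart from an effect of dexamethasone for any gene or list below. Words such as rose and fell describe dexamethasone arrays against control arrays. Signals are linear intensities on the deposited scale, given as mean ± SD with n = 3 per group. Changes are log2 differences of dexamethasone minus control on log2(signal + 16) with their standard error (SE). Across probe sets, arrays of the same group correlated at 0.939 to 0.971 and arrays of different groups at 0.901 to 0.926.

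Dexamethasone-treated placentas had little signal of the embryonic globins and much higher signals of Tph1 and the steroid enzyme Hsd3b1, while prolactin-family genes went both ways and 15 of 18 measured mitosis genes fell. Hbb-y, a beta-like globin of primitive red blood cells, had a signal of 4608 ± 175 in controls and 43.3 ± 7.91 after dexamethasone, a log2 change of -6.29 ± 0.13 (SE). Tph1, the rate-limiting enzyme of serotonin synthesis, rose from 34.7 ± 13.9 to 1339 ± 258, a log2 change of 4.76 ± 0.23. Of 13577 probe sets, 1680 passed the adjusted threshold, 814 higher and 866 lower after dexamethasone. In 1677 of them the signals of the 3 control and the 3 dexamethasone arrays did not overlap.

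Among the 10 largest rises, Hsd3b1, a hydroxysteroid dehydrogenase of progesterone synthesis, went from 69.5 ± 20.4 to 1996 ± 821 (log2 4.50 ± 0.29, adjusted p = 0.000159). The prolactin-family hormones Prl5a1 (38.9 ± 4.20 to 1097 ± 221; log2 4.32 ± 0.17) and Prl3a1 (241 ± 55.3 to 3497 ± 605; log2 3.78 ± 0.19) rose with adjusted p of 1.02e-05 and 2.9e-05. The diamine oxidase-like gene Doxl1 rose by 3.44 ± 0.14, surfactant protein D (Sftpd) by 3.29 ± 0.32, and the ectonucleotidase Entpd2 by 3.22 ± 0.35. The vitamin D receptor Vdr (log2 3.00 ± 0.56), the platelet-activating factor acetylhydrolase Pla2g7 (2.98 ± 0.16) and the Fc receptor Fcgr3 (2.75 ± 0.32) completed the rises. Vdr missed the threshold without dexamethasone replicate 1 (adjusted p = 0.0569) or dexamethasone replicate 2 (adjusted p = 0.0513).

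The 3 largest falls were embryonic globins. Beside Hbb-y, the alpha-like globin Hba-x fell from 2568 ± 924 to 20.6 ± 9.87 (log2 -6.10 ± 0.31) and Hbb-bh1 from 494 ± 294 to 6.37 ± 2.25 (log2 -4.32 ± 0.41). The collagenase Mmp1a changed by -2.96 ± 0.14, the prolactin-family genes Prl4a1, Prl6a1 and Prl7a1 by -2.58 ± 0.18, -2.52 ± 0.20 and -2.19 ± 0.22. Birc5 (survivin), needed for chromosome segregation, changed by -2.50 ± 0.25. Prostacyclin synthase, Ptgis, fell from 152 ± 26.8 to 18.6 ± 23.5 (log2 -2.47 ± 0.39). Aldh1a3, an enzyme of retinoic acid synthesis, fell from 648 ± 149 to 120 ± 14.6 (log2 -2.27 ± 0.18). Adjusted p over these 10 falls ran from 1.68e-07 for Hbb-y to 0.00777 for Ptgis.

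**Figure D1:**
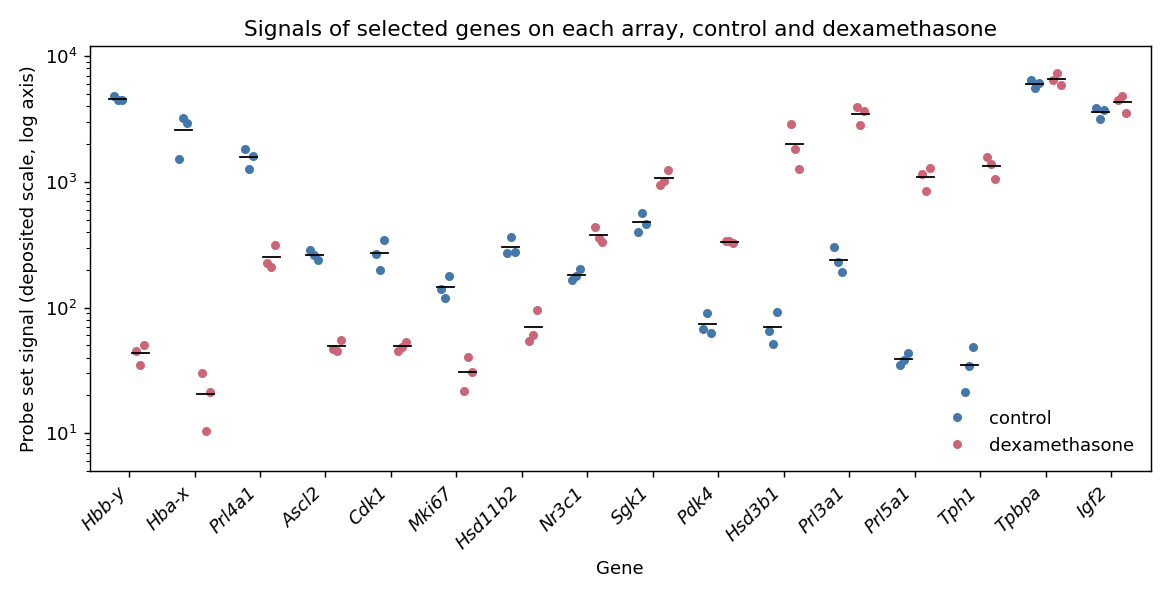
Probe set signal of 16 genes on each of the 6 arrays (log axis, deposited intensity scale), with control arrays in blue, dexamethasone arrays in red and the mean of each group of 3 as a black line. Hbb-y averaged 4608 in controls and 43.3 after dexamethasone and Tph1 34.7 and 1339, while Tpbpa averaged 6058 and 6568.

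Genes known to be induced by glucocorticoids in many tissues rose as a list. Of 26 measured members, 13 rose and 0 fell (15 and 0 adjusted over the list alone), the median log2 change was 0.57, and camera gave an adjusted p of 1.03e-06. The call was lost at an adjusted p = 0.324 with an estimated correlation. Pdk4, a kinase that restrains pyruvate oxidation, rose from 73.5 ± 14.5 to 334 ± 5.67 (log2 1.98 ± 0.15). The transcription factor Cebpd rose by 1.57 ± 0.27, the kinase Sgk1 by 1.15 ± 0.16 (adjusted p = 0.00516) and glutamine synthetase, Glul, by 1.00 ± 0.14. A dimmer Cebpd probe set had a log2 change of -0.05. The treatment checks Fkbp5, Tsc22d3 and Per1 did not pass, Fkbp5 at 0.60 ± 0.17 (adjusted p = 0.0575), Tsc22d3 at 0.35 ± 0.15 (0.152) and Per1 at 0.09 ± 0.15 (0.727).

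Genes that handle glucocorticoids moved both ways. Hsd11b2, which inactivates corticosterone, fell from 305 ± 50.9 to 70.0 ± 22.6 (log2 -1.92 ± 0.20, adjusted p = 0.00158). Hsd11b1, which regenerates it, rose from 428 ± 172 to 1348 ± 469 (log2 1.63 ± 0.29, adjusted p = 0.0124). The glucocorticoid receptor gene Nr3c1 rose from 183 ± 18.7 to 378 ± 55.0 (log2 0.98 ± 0.15, adjusted p = 0.00621). The efflux pump gene Abcb1a rose by 0.54 ± 0.13 and the Hsp90 co-chaperone gene Stip1 changed by -0.84 ± 0.11. In all, 3 of the 10 measured members rose and 2 fell (5 and 2 adjusted over the list alone), with no balance to either side (camera adjusted p = 0.604). Hsd11b1 missed the threshold without control replicate 1 (adjusted p = 0.0584), and Abcb1a missed it whichever array was left out, at up to 0.106.

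Mitosis genes had the lowest median of the 34 lists, a log2 change of -1.32. Of 18 measured members 15 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 1.3e-11), a call lost at adjusted p = 0.336 with an estimated correlation. The cyclin-dependent kinase Cdk1 fell from 270 ± 73.7 to 49.1 ± 3.76 (log2 -2.10 ± 0.19). The proliferation marker Mki67 fell from 146 ± 30.3 to 30.9 ± 9.31 (log2 -1.80 ± 0.20) and Ccnb2 changed by -1.72 ± 0.17. Cdc25b, the phosphatase that rose (log2 0.46 ± 0.13, adjusted p = 0.0499), was chosen after its value was seen. DNA replication genes fell as well, 13 of 25 lower and 0 higher (20 and 0 adjusted over the list alone). The replication median was -0.83 (camera adjusted p = 2.67e-10; adjusted p = 0.324 with an estimated correlation). Mcm5, part of the replicative helicase, went from 84.9 ± 4.37 to 8.57 ± 7.32 (log2 -2.08 ± 0.23). Uhrf1 changed by -1.57 ± 0.16, thymidine kinase Tk1 by -1.51 ± 0.15 and the primase Prim1 by -0.92 ± 0.13. Cell cycle regulators did not move as a list (2 of 21 higher, 1 lower; 2 and 2 adjusted over the list alone; camera adjusted p = 0.885). Within them the cyclin-dependent kinase inhibitor Cdkn1a rose by 0.99 ± 0.17 and the retinoblastoma relative Rbl2 by 0.71 ± 0.15. Skp2, a ubiquitin ligase subunit, changed by -1.21 ± 0.20 (0.04 at a dimmer probe set), and Ccnd3 at -0.49 ± 0.14 did not pass (adjusted p = 0.0559). Cdkn1a and Rbl2 missed the threshold without control replicate 1 or dexamethasone replicate 1, Rbl2 also without control replicate 3, at up to 0.0528 and 0.0885.

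The junctional zone is the hormone-producing layer of spongiotrophoblast and glycogen cells. Of 20 measured markers 3 rose, 5 fell and 12 did not pass (the same numbers adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.793). Prl5a1 and Prl3a1 rose as above, and Ascl2, an imprinted transcription factor of spongiotrophoblast, fell from 263 ± 23.7 to 49.2 ± 5.61 (log2 -2.10 ± 0.14) along with Prl6a1. The remaining members past the threshold, chosen after their values were seen, were Prl8a6 (1.497 ± 0.16), Ncam1 (-1.20 ± 0.20), Ceacam9 (-0.94 ± 0.24) and Prl7d1 (-0.46 ± 0.12). Tpbpa, the standard spongiotrophoblast marker, was at 6058 ± 468 in controls and 6568 ± 767 after dexamethasone (log2 0.11 ± 0.11, adjusted p = 0.536). A dimmer Tpbpa probe set fell by 1.13 ± 0.30 (adjusted p = 0.0427), and another, at 0.32 ± 0.16, did not pass (adjusted p = 0.207). Giant cell markers also went both ways, 3 of 10 higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.317). The leptin receptor Lepr (2.04 ± 0.15) and the cathepsins Cts6 (1.74 ± 0.16) and Ctsr (0.41 ± 0.11) rose, and Prl4a1 and Prl7a1 fell. Another Lepr probe set changed by 0.20, and Ctsr missed the threshold in 5 of the 6 fits with an array left out, at up to 0.159. The giant cell median was 0.22 and the shift against other genes -0.0041. Labyrinth trophoblast markers, from the layer of exchange, had a median of -0.08, with 2 of 20 higher and 1 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.674). The protease inhibitors Spint1 (0.66 ± 0.16) and Spint2 (0.61 ± 0.15) rose and the nuclear receptor Pparg changed by -0.80 ± 0.22. Each of them missed the threshold in at least 4 of the 6 fits with an array left out (adjusted p up to 0.163). Slc16a1, at -0.39 ± 0.11, did not pass (adjusted p = 0.0508).

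Steroid hormone genes rose as a list, 4 of 12 higher and 0 lower (4 and 1 adjusted over the list alone). The median was 0.35 (camera adjusted p = 0.0114; adjusted p = 0.336 with an estimated correlation). The call was also lost with camera on ranks (adjusted p = 0.0546). Beside Hsd3b1, the oestrogen sulphotransferase Sult1e1 rose from 69.4 ± 17.2 to 373 ± 60.9 (log2 2.19 ± 0.18). The side-chain cleavage enzyme Cyp11a1 rose from 295 ± 37.6 to 902 ± 218 (log2 1.54 ± 0.18) and its electron donor Fdx1 by 0.66 ± 0.17. Fdx1 missed the threshold in 5 of the 6 fits with an array left out (up to 0.113).

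The list of insulin-like growth factor axis genes rose, 6 of 19 members higher and 1 lower (8 and 2 adjusted over the list alone). Its median was 0.30 (camera adjusted p = 0.00966; adjusted p = 0.336 with an estimated correlation). The binding protein Igfbp3 rose from 80.8 ± 29.3 to 315 ± 25.8 (log2 1.82 ± 0.21), the protease Htra1 by 1.28 ± 0.19, and the receptor adaptor Grb10 by 0.93 ± 0.16. The kinase Akt1 was the member that fell (715 ± 42.3 to 357 ± 39.7; log2 -0.98 ± 0.13). Igf2 itself had a log2 change of 0.25 ± 0.14 (adjusted p = 0.259). The list mixes ligands, receptors, binding proteins and kinases, so its rise gives no direction of signalling. Imprinted genes did not pass as a list, 3 of 26 higher and 3 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.885). Their median was 0.06 and their mean -0.05, and the direction of camera was opposite to that of fry. Ascl2, Phlda2 (353 ± 72.8 to 121 ± 34.4; log2 -1.44 ± 0.22), which restrains placental growth, and its neighbour Slc22a18 (-0.97 ± 0.15) fell. Grb10, decorin Dcn (0.81 ± 0.15) and Cd81 (0.66 ± 0.17) rose. Cd81 missed the threshold whichever array was left out, at up to 0.114.

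Among transporters, lipoprotein lipase Lpl rose from 296 ± 154 to 1554 ± 483 (log2 2.39 ± 0.35). The calcium channel Trpv6 rose by 1.14 ± 0.15, the cholesterol exporter Abca1 by 0.88 ± 0.15 and the fatty acid binding protein Fabp3 by 0.87 ± 0.10. The list of glucose, lipid, ion and vitamin transporters had 6 of 29 members higher and 1 lower (7 and 2 adjusted over the list alone). Its median was 0.14 (camera adjusted p = 0.0446; adjusted p = 0.336 with an estimated correlation). The lower member, the carnitine transporter Slc22a5 (-0.46 ± 0.11), was chosen after its value was seen. The glucose transporters Slc2a1 (0.23 ± 0.13, adjusted p = 0.286) and Slc2a3 (-0.29 ± 0.15, adjusted p = 0.236) did not pass. Of 17 amino acid transporters Slc1a4 rose (33.2 ± 9.11 to 122 ± 32.9; log2 1.47 ± 0.23) and 0 fell (1 and 0 adjusted over the list alone). The lowest of the other Slc1a4 probe sets was at 0.71. Slc7a8, Slc7a5 and Slc6a6 had log2 changes of 0.59, 0.51 and 0.47 without passing. The amino acid list had a median of 0.21 (camera adjusted p = 0.0454; adjusted p = 0.383 with an estimated correlation). Both transporter lists missed the threshold without control replicate 1 (adjusted p = 0.0595 and 0.0889), dexamethasone replicate 2 (0.0777 and 0.116) or dexamethasone replicate 3 (0.0585 and 0.0627). Over all 20 settings their adjusted p ran from 0.0247 to 0.0888 and from 0.0272 to 0.121. The amino acid list was not called by the directional p of fry (adjusted p = 0.0695).

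Transcripts of the respiratory chain were lower by a small and widely shared amount. Of 77 measured oxidative phosphorylation genes 18 fell and 0 rose (31 and 0 adjusted over the list alone), and 66 had a change below 0. Their median was -0.34 (camera adjusted p = 8.43e-09; adjusted p = 0.336 with an estimated correlation). The ATP synthase subunits Atp5e (-0.84 ± 0.16) and Atp5k (-0.70 ± 0.13), the succinate dehydrogenase subunit Sdhb (660 ± 24.0 to 377 ± 81.9; log2 -0.80 ± 0.16) and Ndufs5 of complex I (-0.63 ± 0.13) fell. Ribosomal protein genes fell with them, 8 of 46 lower and 0 higher (9 and 0 adjusted over the list alone; median -0.28; camera adjusted p = 4.07e-05; adjusted p = 0.454 with an estimated correlation). By its directional p, fry did not call the ribosomal list (adjusted p = 0.0702). Rpsa changed by -0.66 ± 0.11, Rps4l by -0.89 ± 0.18, Rpl6 by -0.49 ± 0.10 and Rpl37 by -0.59 ± 0.12. Bright probe sets in general had lower changes than dim ones: of 8 equal classes of brightness, the dimmest had a median log2 change of 0.07 and the brightest of -0.08. Fatty acid oxidation genes fell too, 4 of 22 lower and 0 higher (8 and 0 adjusted over the list alone; median -0.22; camera adjusted p = 0.0127; adjusted p = 0.348 with an estimated correlation). Acaa2 (-0.95 ± 0.22), Eci2 (-0.60 ± 0.13), Acat1 (-0.54 ± 0.14) and Ech1 (-0.48 ± 0.12) were those 4. The proteasome list was shifted down (median -0.24; camera adjusted p = 0.0039; adjusted p = 0.336 with an estimated correlation). Of its 40 members, however, 1 fell, Psma4 (-0.48 ± 0.11), and 3 rose, Psmd1 (0.87 ± 0.20), Psme4 (0.63 ± 0.15) and Psmd8 (0.61 ± 0.14). Other probe sets of Psme4 were at 0.11 and 0.24 and a dim probe set of Acat1 was at -0.09. The proteasome numbers were the same adjusted over the list alone. Every gene named from these lists missed the threshold without control replicate 1, and all but Rpsa also without at least 1 other array, at an adjusted p of up to 0.122 for Acat1. Cholesterol biosynthesis genes did not pass as a list (median -0.08; camera adjusted p = 0.317), with 0 of 18 higher and 2 lower (1 and 3 adjusted over the list alone). Dhcr7 changed by -1.03 ± 0.23 and Hsd17b7 by -0.89 ± 0.22, and both missed the threshold without control replicate 1 among other arrays (up to 0.0889 and 0.106). Fdft1 at 0.70 ± 0.20 and Sqle at -0.64 ± 0.20 did not pass (adjusted p = 0.0516 and 0.0693).

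Markers of other cell types differed between the groups as well. Erythroid markers fell through the 3 embryonic globins, the carbonic anhydrase Car2 (4098 ± 491 to 1579 ± 282; log2 -1.37 ± 0.15) and Ermap (-1.27 ± 0.18), while 0 of 12 rose (5 lower and 0 higher adjusted over the list alone). Their median was -0.18 and their mean -1.57, with camera adjusted p = 0.00232 and adjusted p = 0.336 with an estimated correlation. Ranks ended this call too (adjusted p = 0.0888). Yolk sac endoderm markers rose, with 3 of 22 higher and 0 lower (6 and 1 adjusted over the list alone), and 20 lay above 0. Their median was 0.68 (camera adjusted p = 0.00129; adjusted p = 0.643 with an estimated correlation). Apolipoprotein B, Apob, went from 1219 ± 345 to 3849 ± 983 (log2 1.66 ± 0.24) and Spink1 from 906 ± 467 to 2315 ± 356 (log2 1.46 ± 0.33). Entpd2 rose as above, and fibrinogen Fgb, at 1.68 ± 0.48, did not pass (adjusted p = 0.0551). The mean of the yolk sac markers relative to all arrays was -1.13 on control replicate 2, 0.22 on control replicate 3 and 0.03 on dexamethasone replicate 3, so the groups overlapped on this measure. An exact permutation test of this mean gave p = 0.2, and fry did not call the list (adjusted p = 0.256). Spink1 missed the threshold without control replicate 1, dexamethasone replicate 1 or dexamethasone replicate 2 (up to 0.0898).

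Uterine natural killer cell markers, the granzymes and their partners, had a median of -0.998 and all 8 measured members below 0. By limma 0 of them passed the threshold, also when adjusted over the list alone, and 4 had an unadjusted p under 0.05. Gzmb went from 244 ± 160 to 82.0 ± 31.0 (log2 -1.29 ± 0.38, adjusted p = 0.0614) and Gzmd from 2556 ± 1091 to 1199 ± 933 (-1.29 ± 0.50). Gzmc went from 567 ± 444 to 219 ± 145 (-1.24 ± 0.53) and Il2rb from 134 ± 36.9 to 83.1 ± 17.2 (-0.58 ± 0.21). The list was shifted down (camera adjusted p = 0.0114; adjusted p = 0.604 with an estimated correlation). It missed the threshold without dexamethasone replicate 2 (adjusted p = 0.0865; range 6.59e-06 to 0.0865 in 20 settings). Its mean relative to all arrays was 1.31 on control replicate 2 against -0.01 and 0.13 on the other controls. It was 0.30 on dexamethasone replicate 3 against -0.68 and -1.05 on dexamethasone replicates 1 and 2. An exact permutation test of this mean gave p = 0.3, and fry did not call the list (adjusted p = 0.246). Control replicate 2 and dexamethasone replicate 3 also stood apart in sex-linked transcripts, with Xist at 2120 and 1775 against 258 to 587 on the other arrays. The Y-linked Eif2s3y was at 1.70 and 0.80 against 87.0 to 164.

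Decidua markers went both ways, with 3 of 15 higher and 2 lower (5 and 2 adjusted over the list alone; median 0.13; camera adjusted p = 0.201). Igfbp1 rose from 105 ± 54.0 to 383 ± 79.6 (log2 1.80 ± 0.31), Adamts1 by 1.13 ± 0.21 and Cryab by 0.61 ± 0.16. Ptgis and Prl3c1 (714 ± 94.8 to 269 ± 82.6; log2 -1.39 ± 0.20) fell. Endothelial markers rose as a list, 2 of 15 higher and 0 lower (6 and 1 adjusted over the list alone; median 0.42; camera adjusted p = 0.00558; adjusted p = 0.361 with an estimated correlation). Plvap, a component of endothelial fenestrae, rose by 1.28 ± 0.24 and endoglin, Eng, by 0.74 ± 0.16, and Ramp2 at 0.46 and Sox17 at 0.70 did not pass. Leukocyte markers rose, 5 of 17 higher and 0 lower (5 and 0 adjusted over the list alone; median 0.26; camera adjusted p = 0.0126; adjusted p = 0.336 with an estimated correlation). Those 5 were Fcgr3, the complement genes C1qc (1.43 ± 0.23) and C1qb (0.71 ± 0.19), cathepsin S, Ctss (1.41 ± 0.25), and lysozyme, Lyz2 (0.90 ± 0.22). Mesenchyme and matrix genes rose, 4 of 27 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.26; camera adjusted p = 0.0303; adjusted p = 0.336 with an estimated correlation). The members that rose were Timp3 (1.63 ± 0.21), Pdgfrb (0.91 ± 0.14), Dcn and Pdgfra (0.72 ± 0.15). The lowest of the other Timp3 probe sets was at 0.54. The leukocyte list missed the threshold without dexamethasone replicate 3 (adjusted p = 0.0732; range 0.00213 to 0.0732). The mesenchyme list missed it without control replicate 2 (0.079) or dexamethasone replicate 2 (0.0796), and with the mean over the probe sets of a gene (0.135; range 0.00742 to 0.135). By its directional p, fry called none of the endothelial (adjusted p = 0.0702), leukocyte (0.0783) and mesenchyme (0.0544) lists. Of the genes named here, Adamts1, Cryab, Plvap, Eng, Ctss, Lyz2, C1qb and Pdgfra missed the threshold without control replicate 1, and all but Plvap and Ctss also without another array (adjusted p up to 0.143).

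**Figure D2:**
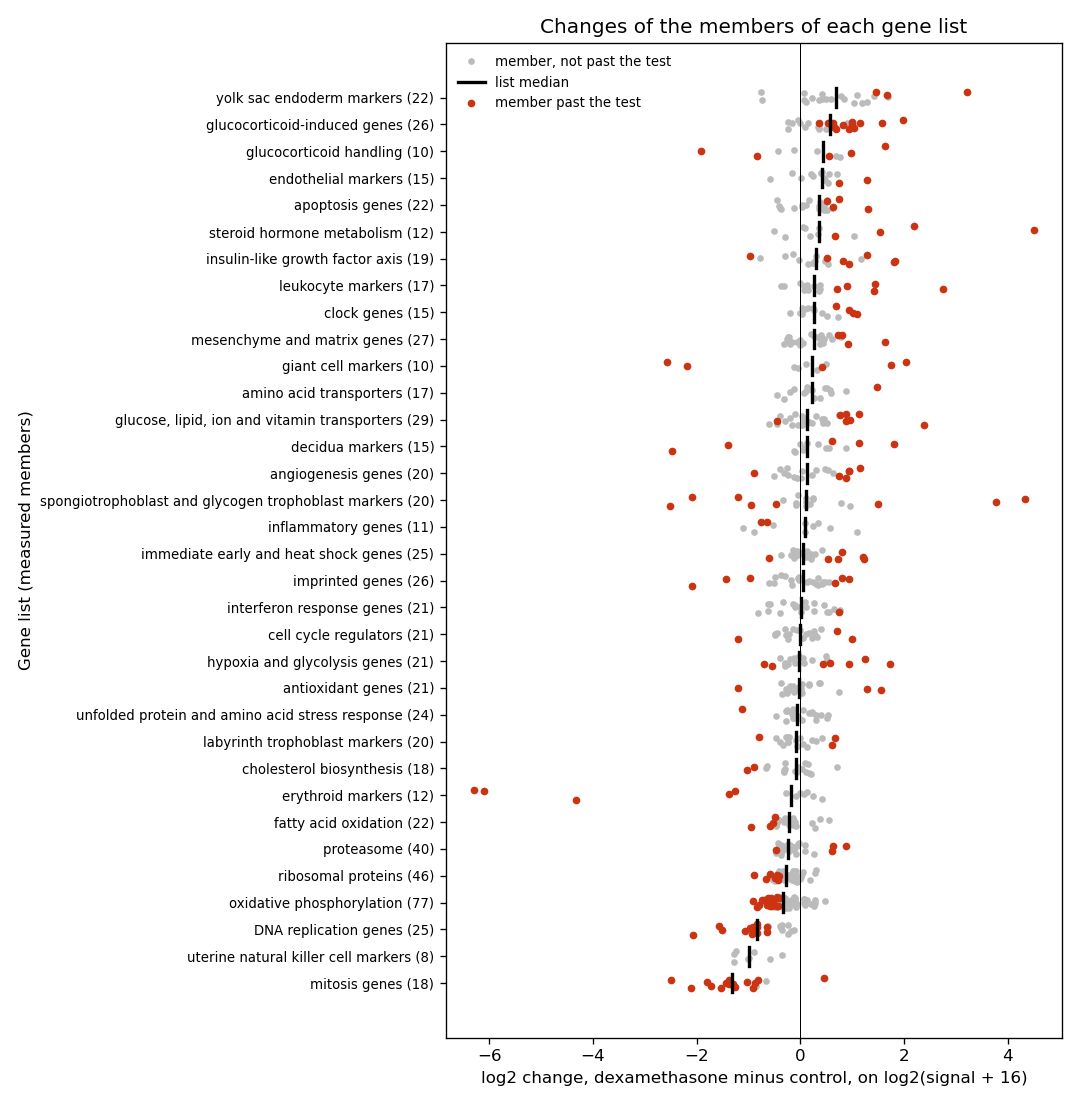
Log2 change (dexamethasone minus control, on log2(signal + 16)) of each measured member of the 34 gene lists, with members past the adjusted threshold in red, other members in grey and the median of each list as a black bar. Mitosis genes had a median of -1.32 and DNA replication genes of -0.83, the yolk sac endoderm list had the highest median, 0.68, and spongiotrophoblast markers held 3 members that rose and 5 that fell.

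Genes of blood vessel growth did not pass as a list (median 0.13; camera adjusted p = 0.26), with 5 of 20 higher and 1 lower (6 and 2 adjusted over the list alone). Angpt2, an antagonist of vessel stability, changed by -0.90 ± 0.14. Pdgfb (1.15 ± 0.23), placental growth factor Pgf (0.94 ± 0.19), adrenomedullin Adm (0.94 ± 0.23), endothelin Edn1 (0.89 ± 0.22) and Eng rose. A dimmer Pdgfb probe set was at 0.47. Vegfa, at 137 ± 10.2 and 202 ± 60.3, did not pass (log2 0.48 ± 0.19, adjusted p = 0.137). Hypoxia and glycolysis genes had a median of -0.02 and a mean of 0.15, with 5 of 21 higher and 2 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.826). The glycolytic enzymes Pkm (-0.69 ± 0.12) and Tpi1 (-0.55 ± 0.13) fell, and Egln3, an oxygen-sensing hydroxylase, and Pfkfb3, an activator of glycolysis, rose by 1.73 ± 0.29 and 1.25 ± 0.21. Adm and, chosen after their values were seen, Bnip3 (0.57 ± 0.14) and Ndrg1 (0.43 ± 0.12) were the remaining rises. Angpt2, Pkm, Egln3 and Pfkfb3 passed whichever array was left out. The other genes named by the rule here missed the threshold without control replicate 1 among other arrays (adjusted p up to 0.117).

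Apoptosis genes rose as a list, 4 of 22 higher and 0 lower (7 and 4 adjusted over the list alone; median 0.37; camera adjusted p = 0.0316; adjusted p = 0.336 with an estimated correlation). This list missed the threshold without dexamethasone replicate 3 (adjusted p = 0.0653) and with the filter at the 60th percentile (0.101; range 0.0236 to 0.101). The 4 were Pmaip1 (72.2 ± 18.6 to 198 ± 13.4, log2 1.30 ± 0.18), Bbc3 (0.75 ± 0.18), Bik (0.63 ± 0.17) and Bid (0.50 ± 0.12), which promote cell death. The other members past the list-alone threshold were chosen after their values were seen. Bcl2l1 (0.45), Mcl1 (0.46) and Birc3 (0.60), which restrain cell death, rose. Casp9 (-0.42), Casp6 (-0.40), Cycs (-0.375) and Aifm1 (-0.44), which promote it, fell. The rise of the list therefore gives no direction of cell death. Clock genes rose too, 4 of 15 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.26; camera adjusted p = 0.0069; adjusted p = 0.336 with an estimated correlation). The clock list missed the threshold with the filter at the 60th percentile (adjusted p = 0.122). It had been fixed as a check of the time of collection, so a difference between the groups in that time is not excluded. The 4 clock genes were Nr1d2 at 1.09 ± 0.16, Cry2 at 1.01 ± 0.27, Npas2 at 0.94 ± 0.24 and Dbp at 0.68 ± 0.16. Immediate early and heat shock genes did not pass as a list with camera (median 0.06, camera adjusted p = 0.126). By the directional p of fry the list was called higher (adjusted p = 0.0322). Of its members, 5 of 25 were higher and 1 lower (5 and 1 adjusted over the list alone). The transcription factors Klf2 (1.20 ± 0.15), Klf4 (0.80 ± 0.14) and Fos (0.72 ± 0.15), Ier3 (1.23 ± 0.21) and the phosphatase Dusp1 (0.54 ± 0.13) rose. The chaperone Hsph1 changed by -0.60 ± 0.15. The immediate early and heat shock list had been fixed as a check of tissue handling, and a difference in handling between the groups is not excluded either. Of the genes named by the rule here, Pmaip1, Nr1d2, Klf2, Klf4 and Ier3 passed whichever array was left out. The others missed the threshold without control replicate 1 among other arrays (adjusted p up to 0.142).

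Inflammatory, interferon, antioxidant and protein-folding stress genes did not pass as lists. Inflammatory genes had 0 of 11 higher and 2 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.604), with a median of 0.09 and a mean of -0.14. The adhesion molecule Icam1 (-0.76 ± 0.17) and interleukin Il1a (-0.64 ± 0.17) fell. Cxcl12 at -0.90 ± 0.25 and Il1r1 at -1.11 ± 0.33 did not pass (adjusted p = 0.0517 and 0.0607). Interferon response genes had 1 of 21 higher, Ifit1 (0.75 ± 0.14), and 0 lower (3 and 1 adjusted over the list alone; median 0.01; camera adjusted p = 0.826). Stat2, B2m and Gbp2 had changes of -0.63, 0.45 and 0.76 without passing. Antioxidant genes had a median of -0.03 and a mean of 0.07, with 2 of 21 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.889). Gclc, which limits glutathione synthesis, rose from 105 ± 11.9 to 347 ± 82.3 (log2 1.56 ± 0.19) and Sod3 by 1.27 ± 0.30. Haem oxygenase, Hmox1, fell from 665 ± 60.4 to 281 ± 50.1 (log2 -1.21 ± 0.15). The unfolded protein and amino acid stress list had 0 of 24 higher and 1 lower (0 and 1 adjusted over the list alone; median -0.07; camera adjusted p = 0.885). The lower gene was Sdf2l1 (-1.13 ± 0.19), and Ddit3 (0.53), Dnajc3 (-0.47) and Atf5 (0.40) did not pass. Gclc, Hmox1 and Sdf2l1 passed whichever array was left out, and Icam1, Il1a, Ifit1 and Sod3 missed the threshold without control replicate 1 among other arrays (adjusted p up to 0.147).

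By gene, 1120 of 8371 passed the limma test, 571 higher and 549 lower, and 57 probe sets differed at least 4-fold, 34 higher and 23 lower. At an unadjusted p under 0.05 with at least 1.5-fold change there were 1865 probe sets, 1039 higher and 826 lower (1050 in all with a pseudocount of 64). The groups did not overlap in 35.4% of all probe sets, where chance gives 10%. Of the 34 lists, camera with the preset correlation called 19 (11 higher, 8 lower), and fry called 13 by its directional p. The lists that camera called and fry did not were amino acid transporters, ribosomal proteins, and the endothelial, leukocyte, mesenchyme, yolk sac and natural killer lists. By its mixed p, which does not compare a list with other genes, fry called 33. With an estimated correlation camera called 0, and 4 lists had an unadjusted p under 0.05. The number of probe sets past the threshold was 468 without control replicate 1, 989 without control replicate 2, 964 without control replicate 3, 551 without dexamethasone replicate 1 and 994 without dexamethasone replicate 2, while 71 of the 127 named genes past the threshold passed whichever array was left out. When the 6 arrays were split in the 9 other ways into 3 and 3, limma called 0 probe sets (100 to 564 had an unadjusted p under 0.05) and fry 0 lists. Camera with the preset correlation still called 2 to 16 lists. These splits mix the 2 groups on both sides, which widens the spread, so the 0 calls of limma and fry do not measure false calls.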

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

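The Xist covariate and cyclic loess were chosen after the results were seen. All 1680 probe sets past the threshold kept their direction in each of the 18 other settings that tested them, and 0 named genes or lists past the threshold reversed. For the probe sets this was largely fixed in advance. The groups did not overlap in 1677 of them, so leaving out an array or changing the pseudocount cannot reverse these. Array weights raised the number of probe sets past the threshold to 2945 (1388 higher, 1557 lower). Leaving out an array gave 468 to 1772 probe sets, 254 to 907 higher and 214 to 865 lower: 468 without control replicate 1, 989 and 964 without control replicates 2 and 3, and 551, 994 and 1772 without dexamethasone replicates 1, 2 and 3, with fewer samples in each fit. The remaining settings gave 1176 to 1719. A pseudocount of 64 lowered the number at an unadjusted p under 0.05 with at least 1.5-fold change from 1865 to 1050, since it compresses the change of dim probe sets. Centring on the array median made 39.6% of the calls higher, against 48.5%, while cyclic loess made 54.1% and the Xist covariate 52.6% higher, so which direction had more calls depended on the setting. An estimated correlation left 0 of 19 lists past the threshold, with a smallest adjusted p of 0.324. The size of the correlation does not account for every loss. It was estimated at -0.011 for the insulin-like growth factor axis and -0.022 for apoptosis genes, below the preset 0.01, and both calls were lost (camera adjusted p = 0.336). With an estimated correlation camera also uses the few residual degrees of freedom of these arrays, which weakens the test of every list. A call lost in that setting is therefore not by itself a sign that the genes of the list vary together. Of the 19 lists, 10 passed in all 20 other settings, among them mitosis, DNA replication, oxidative phosphorylation and ribosomal proteins; amino acid transporters passed in 13 and glucose, lipid, ion and vitamin transporters in 11, and both lost the call without a filter, with array weights and with the Xist covariate. Clock and apoptosis genes lost the call with the filter at the 60th percentile (adjusted p = 0.122 and 0.101), mesenchyme and matrix genes with the mean over the probe sets of a gene (0.135), steroid and erythroid lists with ranks (0.0546 and 0.0888), and natural killer markers without a filter (0.0502); the cause was not tested. Over all 20 settings the adjusted p ran from 0.00397 to 0.122 for clock genes, from 0.00167 to 0.0546 for steroid genes and from 5.28e-05 to 0.0888 for erythroid markers. With an array left out, 72 to 108 of 127 named calls were kept. The replicate block gave 1176 probe sets. Deviations of same-numbered arrays correlated at 0.089, -0.052 and -0.06, and not every array correlated best with its own number. These values show no pairing by number, but deviations from means of 3 arrays cannot exclude one. Dim signals have no detection call, and changes of genes near 16 are understated.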

Other observations

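Chosen after the results were seen were the tests of gene families, of red blood cells, yolk sac, decidua and cyclic loess for the ribosomal list, and the count of splits for probe sets. The other tests of explanations below were not in the plan either. Their rules were written for patterns already seen, but before the values that tested them. Among 134 families of genes that share the start of their symbol, the prolactin family was the one with more changed members than the array as a whole after adjustment. Of 15 measured Prl genes 8 changed, 3 higher and 5 lower, where 2.01 would be drawn by chance (one-sided Fisher's exact test for an excess, p = 0.000269, adjusted p = 0.0361). The members spanned a log2 change of 4.32 ± 0.17 for Prl5a1 to -2.58 ± 0.18 for Prl4a1, while the brighter genes Prl2a1 (5073 ± 764 and 4781 ± 722) and Prl8a8 (4137 ± 232 and 4468 ± 327) had changes of -0.09 and 0.11. The serine protease inhibitors of the Serpinb family had 5 of 8 members changed, all lower, without passing the adjustment over families (one-sided Fisher's exact test, p = 0.00168, adjusted p = 0.112). Serpinb9c went from 1145 ± 144 to 375 ± 67.3 (log2 -1.58 ± 0.16), Serpinb9 changed by -0.80 ± 0.16 and Serpinb9g by -0.69 ± 0.13. Cytochrome P450 genes had 6 of 19 members changed, all higher (one-sided Fisher's exact test, p = 0.0327, adjusted p = 0.877).

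The embryonic globins Hbb-y, Hba-x and Hbb-bh1 fell by 4.32 to 6.29 on the log2 scale. Fewer red blood cells of every kind in the treated placentas would lower the other erythroid genes as far. The median of the 9 others was 0.0003, however, and the lowest, Car2, was at -1.37. A loss of primitive red blood cells alone, with other red blood cells kept, was not tested by these values and stays open. Less yolk sac tissue is argued against by its endoderm markers, whose median was 0.68 and lower quartile 0.25; their array means overlapped between groups, the shift against other genes was 0.75 and, without control replicate 2, 0.37, and the rise of the list was not called by fry (adjusted p = 0.256) and was lost at adjusted p = 0.643 with an estimated correlation, but neither shift is a fall. A later stage of maturation, reached through the treatment or through the day of collection, remains a candidate explanation. The 6 measured genes that decline with fetal age had a median of 0.041, and 2 of them were lower. Their scaled median absolute deviation, divided by the root of their number, was 0.14. Of the lower genes Dnmt3b, chosen after its value was seen, passed the threshold (-0.56 ± 0.15, adjusted p = 0.0454). The rule as written counted a median that had not fallen against this explanation. The scoring also asked that the median clear this spread, which it did not, and 6 genes are too few to decide. The labels give no day of collection, so an effect of dexamethasone and a difference in age cannot be told apart here.

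Granzyme and perforin transcripts were lower after dexamethasone with a median of -0.998. Less maternal decidua in the treated samples was not seen in the decidua markers as a list, whose lower quartile was -0.047. These markers cannot decide it, since Prl3c1 (-1.39) and Ptgis (-2.47) fell while Igfbp1, Adamts1 and Cryab rose. The decidua mean relative to all arrays was highest on control replicate 2 (0.16) and dexamethasone replicate 3 (0.18), where the natural killer mean was also highest in each group. One control sample rich in natural killer cells may carry part of the difference: without control replicate 2 the median was -0.52 and the list still passed (camera adjusted p = 0.0467), but the SE of its difference between arrays, 0.52, is too wide to decide. The rule as written would have counted these values against this explanation, and the margin of 1 SE was added in the scoring. With all 6 arrays 0 of the 8 members passed on their own, fry did not call the list (adjusted p = 0.246), and the camera call was lost at adjusted p = 0.604 with an estimated correlation. A loss of these cells under dexamethasone stays open and untested.

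Respiratory chain and ribosomal protein transcripts were lower by a small shared amount, and bright probe sets were lower in general. A difference in scaling that depends on intensity is argued against as the whole cause: after cyclic loess, which removes such a trend, the shift against other genes went from -0.33 to -0.29 for the respiratory chain (adjusted p = 3.92e-07) and from -0.27 to -0.23 for ribosomal proteins (adjusted p = 0.000666). Without cyclic loess both calls were lost, at adjusted p = 0.336 and adjusted p = 0.454 with an estimated correlation. By its directional p fry called the respiratory chain list lower (adjusted p = 0.0307) but not the ribosomal list (adjusted p = 0.0702). A coordinated response to dexamethasone is a hypothesis that these values leave open, and a change in the mix of cells was not tested.

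Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probe sets past the threshold as the treatment groups, the real one, with 1680 against 0 in the highest of the others. For the lists tested with camera, 1 of the 10 splits likewise gave as many, the real one, with 19 against 16. A share under 0.05 cannot be reached with 10 splits. Each of the other splits also has control and dexamethasone arrays on both sides, so the difference between the groups widens its spread. Their 0 probe sets are therefore no measure of how many calls arise by chance.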
